A study of Mus musculus with 19 samples.

How the data were processed

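Thymocytes were sorted from WT mice and from mice with a loxP-flanked Rptor gene and a CD2-driven Cre recombinase, which removes Rptor (the gene of the mTORC1 subunit Raptor) in lymphocytes. Per the labels' protocols DN3a cells were CD25-high, CD44-negative and CD28-negative, ISP cells CD4-negative, CD8-positive and TCRβ-negative, and γδ T cells were gated without CD4, CD8, TCRβ, NK1.1 and Gr1. Per the labels, 12 ng of RNA was used per array. Groups and replicate numbers came from the sample titles, which gave 4 WT and 3 Rptor−/− ISP arrays and 3 arrays of each genotype for DN3a and γδ T cells.

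The deposited values were log2 expression values per probe set for 19 arrays. Per the submitters' processing notes they were made with RMA (background correction, quantile normalization and probe summary) in Partek 6.6; which arrays were normalized together is not given in the sources used here. The values themselves fell into 2 sets. Medians were 3.80 to 3.88 on the 7 ISP arrays and 6.03 to 6.13 on the 12 DN3a and γδ arrays, so the table was treated as holding 2 separate normalizations. Genotype comparisons lie within 1 set. Comparisons of WT ISP cells with the other cell types cross the sets, and for these only counts are given: their genes and lists, planned before the data were examined, were left out because nearly every gene differed. The values were used as deposited with no filter on low signal. A probe set that measures weak signal gives a compressed fold change on such arrays, and the number of arrays limits precision. The median SD of a gene within a group was 0.0883 to 0.117 log2 units.

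Of 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 were not named in the probe annotation used here; the latter 2 kinds were left out. Symbols were updated through Entrez IDs for 23328 probe sets with a RefSeq gene table of mouse assembly GRCm38.p6, which was also used for gene order along chromosomes, and no coordinates are given. Of 22180 genes, 1082 had more than 1 probe set and were represented by the one with the highest mean over all arrays.

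Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 model of 6 group means over all 19 arrays, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. There were 3 genotype comparisons, 3 comparisons of WT cell types and 3 interactions (differences of genotype effects). The cell types share no arrays between genotype comparisons. Every adjusted p of a gene is limma's. Rptor was also tested with an exact two-sided permutation test. Overlaps of changed genes used Fisher's exact test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

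Before the data were examined 27 gene lists were fixed from textbook knowledge, with 703 entries of which 627 were measured. They covered MYC targets and ribosome biogenesis, cholesterol and fatty acid synthesis, ATF4 and amino acid supply, glycolysis, the TCA cycle, oxidative phosphorylation, antioxidant genes, lysosome and autophagy, mTORC components, FOXO targets, S phase, G2/M, p53 targets, interferon response, TCR signal strength, Notch and DN3 genes, αβ-lineage, γδ-lineage, cytotoxic genes, sex-linked genes, and markers of B cells, dendritic cells, erythroid cells, mature αβ T cells, myeloid cells and thymic stroma. Sex-linked genes, with 4 measured, were given one by one, and 26 lists were tested with camera in limma with a preset correlation between genes of 0.01. A list's value is the median log2 difference of its genes. With the correlation estimated per list instead, 8 of 15 list calls held in ISP cells, 1 of 5 in DN3a cells, 0 of 9 in γδ T cells and 7 of 12 between WT γδ and DN3a cells; with fry, which tests whether a list's genes move one way on balance, 13, 3, 7 and 11 held. For γδ T cells 8 lists had an unadjusted p under 0.05 with the estimated correlation. The median and the mean of a list differed in sign for 2, 4, 1 and 1 lists in these 4 comparisons.

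Named genes were chosen by a rule fixed in advance. It took Rptor, the 8 higher and 8 lower genes with the largest change in each genotype comparison and the 6 in each direction between WT cell types, among genes past the threshold whose groups did not overlap, the 4 with the smallest p in each direction of each interaction, and up to 4 genes with the smallest p per list. Predicted genes, clone names, olfactory and vomeronasal receptor genes, microRNA and small nucleolar RNA genes, pseudogenes of ribosomal proteins and receptor segments were passed over in the rule's ranked parts. From the lists, genes whose calls held with each array left out were preferred as examples. Named after their values were seen, outside the rule, were Eif4a1, Idh2 and Nr4a1 in ISP cells, Gzma and Klre1 in γδ T cells, and the values of Kit in single populations.

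The fits were first tested on simulated data of 22180 genes in which known changes were put into some genes. The noise was drawn independently for each gene, so the rates below describe simpler data than the real arrays. Of 100 genes changed by 0.5 log2 units, 63, 69 and 62 were recovered in the ISP, DN3a and γδ designs, and of 100 changed by 1 log2 unit, 97, 97 and 98. False calls made up 6.98%, 3.49% and 4.76% of calls.

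Alternatives fixed in advance were quantile normalization across all arrays, median centring of arrays, removal of genes below the median level, the mean of a gene's probe sets or every probe set alone, a fit of only the arrays compared, a trended and robust variance model, array weights, a minimum of 2-fold, the replicate number as a block, an estimated correlation or fry for lists, and leaving out each array in turn. A fit of only the 12 DN3a and γδ arrays was added after seeing the data.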

Results

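Gene expression was measured on 19 microarrays of sorted mouse thymocytes from 3 developmental populations, each taken from wild-type (WT) animals and from animals lacking Rptor in lymphocytes. Rptor encodes Raptor, the defining subunit of the kinase complex mTORC1. DN3a cells are CD4/CD8 double-negative thymocytes at the stage where αβ and γδ T cells part, immature single-positive (ISP) cells are CD8-positive thymocytes on the αβ branch before the double-positive stage, and γδ T cells were gated as negative for CD4, CD8, TCRβ, NK1.1 and Gr1. There were 4 WT and 3 Rptor−/− ISP arrays, and 3 arrays of each genotype for DN3a and for γδ T cells. After reduction to 1 probe set per gene, 22180 genes were compared. Array medians were 3.80 to 3.88 log2 units on the 7 ISP arrays and 6.03 to 6.13 on the other 12, so ISP arrays were read against ISP arrays. The number of arrays limited the precision. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

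The targeted gene was examined first. Rptor signal was lower in the Rptor−/− arrays of every population by limma. In DN3a cells it was 9.65 ± 0.10 log2 units in Rptor−/− and 10.23 ± 0.09 in WT arrays (SD, n = 3 each), a log2 difference of −0.58 (limma adjusted p = 6.0e-04) that left 66.9% of the WT signal. In γδ T cells it was 9.47 ± 0.06 against 9.77 ± 0.03 (SD, n = 3 each), a difference of −0.30 (limma adjusted p = 0.049) that left 81.2%. In ISP cells it was 6.20 ± 0.14 (SD, n = 3) against 6.44 ± 0.07 (SD, n = 4), a difference of −0.24 (limma adjusted p = 0.038) that left 84.4%. Exact two-sided permutation tests on single values gave p = 0.1 in DN3a and in γδ T cells, the smallest that 3 arrays against 3 allow, and p = 0.114 in ISP cells, where the smallest possible was 0.0571. The γδ call was lost when any 1 of its 6 arrays was left out (adjusted p from 0.0713 to 0.156, values from −0.33 to −0.27). The ISP call was lost without Rptor−/− array 1 (−0.18), Rptor−/− array 2 (−0.24) or WT arrays 1 (−0.23), 2 (−0.24) or 4 (−0.23). Rptor was read by 1 probe set, which may lie outside the deleted part of the gene, so residual signal is no measure of deletion.

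**Figure D1:**
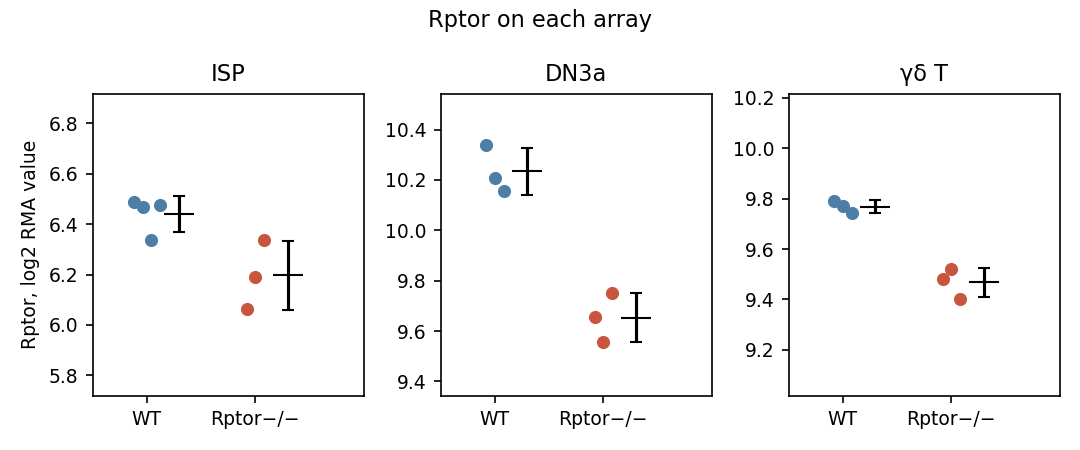
Rptor signal (log2 RMA value) on each array, with WT in blue, Rptor−/− in red and the group mean ± SD in black, for ISP cells, DN3a cells and γδ T cells; each panel spans the same number of log2 units. The 3 DN3a Rptor−/− arrays lie below all 3 WT arrays, with means of 9.65 and 10.23, and the ISP groups have means of 6.20 and 6.44.

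The comparison of Rptor−/− with WT ISP cells asked what differed with Rptor genotype in cells on the αβ branch. The activity of mTORC1 was not measured. Lists of cholesterol and fatty acid synthesis, ribosome biogenesis, oxidative phosphorylation and glycolysis were lower in Rptor−/− ISP cells by camera, and these calls held (adjusted p from 0.00839 to 0.0229 with an estimated correlation). The lowest single genes were Hspa1a and Hspa1b, which encode the inducible heat shock protein Hsp70, at −4.74 (SE 0.58) and −4.67 (SE 0.67) on the log2 scale; their sequences are nearly identical and the 2 signals cannot be assumed to be separate. Higher genes included Dtx1, a target and regulator of Notch signalling, at 1.81 (SE 0.10), and Ets2, a transcription factor, at 1.57 (SE 0.09). By limma 2759 genes changed, 1302 higher and 1457 lower in Rptor−/−, and 112 of them by at least 2-fold (52 higher, 60 lower). Over all genes, called or not, groups did not overlap for 16.7%, which chance gives for 5.71%.

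Among the other genes with the largest rise in Rptor−/− ISP cells were Txk, a Tec family kinase of T-cell receptor signalling (1.93, SE 0.20), Tox2, a relative of the transcription factor Tox (1.73, SE 0.14; WT array 2 lay apart from the other 3), and Sidt1, a transmembrane protein of the SID1 family (1.72, SE 0.10). The class I-like gene H2-T10 rose by 1.51 (SE 0.14) and the tetraspanin gene Tspan32 by 1.51 (SE 0.12). Nnat, an imprinted gene, had the largest rise at 4.10 (SE 0.63), but Rptor−/− arrays varied by an SD of 2.50 around their mean of 8.96, against 0.24 around 4.86 in WT, and the call was lost when only ISP arrays were fitted (adjusted p = 0.0697). Among the genes that fell were Jun (−3.25, SE 0.28) and Fos (−2.30, SE 0.20), which encode the AP-1 transcription factor, Id3, an inhibitor of E proteins that T-cell receptor signals induce (−2.29, SE 0.12), Dnajc15, a mitochondrial co-chaperone (−2.03, SE 0.13), Fads2, the delta-6 fatty acid desaturase (−1.70, SE 0.10), and the chaperone gene Hsph1 (−1.70, SE 0.17). Sidt1 was 0.95 higher when all probe sets of the gene were averaged. The limma adjusted p of these genes ranged from 1.1e-09 for Dtx1 and Id3 to 1.4e-04 for Nnat.

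The lists of lipid synthesis genes fell. In cholesterol synthesis and SREBP2 targets, 15 of 19 measured genes were lower, none was higher and 4 did not pass (17 lower adjusted over the list alone), with a median of −0.67 (camera adjusted p = 5.96e-23). Sqle, squalene epoxidase, was at −1.39, Fdps, farnesyl diphosphate synthase, at −1.39 and Msmo1, a methylsterol oxidase, at −1.29. In fatty acid synthesis and SREBP1 targets, 10 of 16 were lower, none was higher and 6 did not pass (11 lower adjusted over the list alone), with a median of −0.32 (camera adjusted p = 2.72e-09). Besides Fads2, the elongase gene Elovl6 fell by 0.74 and Fasn, fatty acid synthase, by 0.61.

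Lists of protein synthesis and amino acid supply also fell. Of 37 MYC targets and ribosome biogenesis genes, 31 were lower, 1 was higher and 5 did not pass (33 lower and 1 higher adjusted over the list alone), with a median of −0.44 (camera adjusted p = 1.48e-25). Examples were Ddx21, a nucleolar RNA helicase (−0.81, SE 0.08), Rrp9, a component of the ribosomal RNA processing machinery (−0.74, SE 0.08), and Rrp12, needed for export of ribosomal subunits (−0.93, SE 0.10). The exception was Eif4a1, a translation initiation helicase, at 0.57 (SE 0.11). Of 30 genes of ATF4, serine and one-carbon metabolism and amino acid transport, 16 were lower, none was higher and 14 did not pass (16 lower adjusted over the list alone), with a median of −0.27 (camera adjusted p = 6.28e-11). Slc7a5, a subunit of the large neutral amino acid transporter, fell by 0.85, and Shmt2 and Mthfd2, mitochondrial one-carbon enzymes, fell by 0.65 and 0.52.

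In oxidative phosphorylation 34 of 52 genes were lower, none was higher and 18 did not pass (38 lower adjusted over the list alone), with a median of −0.30 (camera adjusted p = 4.11e-24). Cytochrome c (Cycs) fell by 0.77, the complex I gene Ndufb6 by 0.63 and the complex III gene Uqcrq by 0.84. In glycolysis 10 of 19 were lower and 9 did not pass (12 lower and 1 higher adjusted over the list alone), with a median of −0.23 (camera adjusted p = 6.73e-08). Pfkl, a phosphofructokinase, was at −0.77 and Tpi1, triosephosphate isomerase, at −0.86. The antioxidant and NRF2 list had 6 of 20 lower, none higher and 14 not passing (10 lower adjusted over the list alone; median −0.23, camera adjusted p = 1.55e-07). Its members included Taldo1, transaldolase of the pentose phosphate pathway, at −1.02, and Sod2, mitochondrial superoxide dismutase, at −0.70. In the TCA cycle 9 of 22 were lower, 1 was higher and 12 did not pass (11 lower and 2 higher adjusted over the list alone; median −0.21, camera adjusted p = 2.99e-06, adjusted p = 0.124 with an estimated correlation). Fumarate hydratase (Fh1) was at −0.76, the succinate dehydrogenase genes Sdhb and Sdhd at −0.51 and −0.53, and Idh2 was higher at 0.27, a call lost without Rptor−/− array 1 (0.23) or 2 (0.26). On WT array 4 Fdps, Sod2 and Sdhd lay apart from the other 3 WT arrays.

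In the TCR signal strength and immediate early list 13 of 27 genes fell, 1 rose and 13 did not pass (15 lower and 2 higher adjusted over the list alone), with a median of −0.42 (camera adjusted p = 1.55e-07) that was −0.22 without WT array 4. Besides Id3 and Fos, Nr4a1, which encodes the orphan receptor Nur77, was at −1.30 and Fosb at −1.69, whereas the surface receptor gene Cd6 was at 0.61. Stress at sorting was not ruled out for the heat shock and immediate early genes, since 20 other stress genes had a median of −0.226, 9 lower and none higher. In the αβ-lineage list 12 of 29 were higher, 4 were lower and 13 did not pass (16 higher and 4 lower adjusted over the list alone; median 0.25, camera adjusted p = 1.3e-06, adjusted p = 0.0797 with an estimated correlation). Lef1 and Bcl11b, transcription factors of T-cell commitment, were at 0.68 (WT array 2 lay apart from the other 3) and 0.57, and Id3 belongs to this list too. Among Notch signalling and DN3 genes 7 of 24 were higher, 1 was lower and 16 did not pass (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 7.4e-04, adjusted p = 0.0962 with an estimated correlation). Notch3 was at 1.36 and Hes1, a Notch target, at −0.98; the median of this list, 0.054, was −0.021 without WT array 4. In the type I interferon list 9 of 26 rose, none fell and 17 did not pass (10 higher and 1 lower adjusted over the list alone; median 0.23, camera adjusted p = 6.83e-07, adjusted p = 0.0888 with an estimated correlation). Ddx58, which encodes the RNA sensor RIG-I, was at 0.80 and Trim30a at 0.94. Dendritic-cell and myeloid markers did not move as lists beside them, with medians of −0.075 and −0.0019 (camera adjusted p = 0.416 and 0.786).

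In S phase and DNA replication 14 of 31 genes were lower in ISP cells, none was higher and 17 did not pass (17 lower adjusted over the list alone; median −0.34, camera adjusted p = 6.64e-12, adjusted p = 0.161 with an estimated correlation). Chaf1b, a chromatin assembly factor, was at −0.63, Rfc3, a clamp loader subunit, at −0.67 and Mcm5, part of the replicative helicase, at −0.54. In G2/M and mitosis 4 of 30 were higher, none was lower and 26 did not pass (4 higher adjusted over the list alone; median 0.24, 0.12 without Rptor−/− array 1; camera adjusted p = 9.32e-05, adjusted p = 0.55 with an estimated correlation). The centromere protein gene Cenpf was at 0.99 (SE 0.17). The p53 target list had 4 of 21 higher, none lower and 17 not passing (5 higher adjusted over the list alone; median 0.15, camera adjusted p = 0.0316, adjusted p = 0.36 with an estimated correlation). Its call was lost without Rptor−/− array 3 (median 0.11) or WT array 4 (median 0.12), and when only ISP arrays were fitted. The 2759 changed genes of ISP cells were 1313 when only ISP arrays were fitted, and with each array centred on its median 35.8% of changed genes were higher in place of 47.2%.

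**Figure D2:**
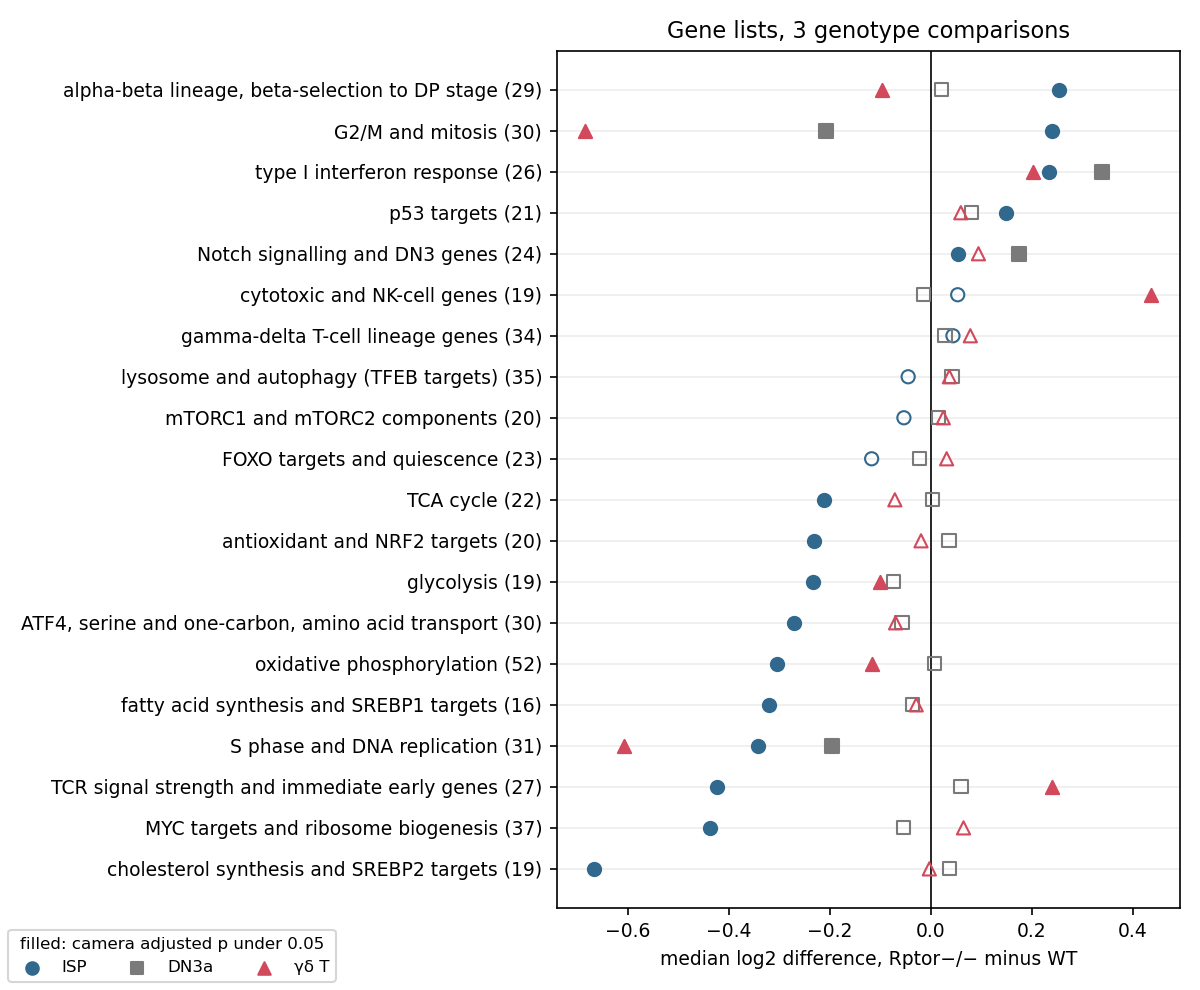
Median log2 difference between Rptor−/− and WT (horizontal axis) of the genes of each list (number measured in parentheses), with circles for ISP cells, squares for DN3a cells and triangles for γδ T cells; filled symbols have a camera adjusted p under 0.05. Cholesterol synthesis lies at −0.67 in ISP cells and G2/M genes at −0.68 in γδ T cells and 0.24 in ISP cells.

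In DN3a cells, the common precursor stage, 218 genes changed with loss of Rptor by limma, 158 higher and 60 lower. The type I interferon list was higher by camera (adjusted p = 5.59e-17, adjusted p = 0.0375 with an estimated correlation). Ifi204, an interferon-inducible p200 family gene, was higher by 1.88 (SE 0.19) on the log2 scale and Trim30c, of an interferon-inducible Trim cluster, by 1.40 (SE 0.13). Dtx1 rose by 1.38 (SE 0.10) and Mpzl2, an adhesion molecule gene, by 1.60 (SE 0.19). Cpa3, a mast-cell protease gene also transcribed in early progenitors, fell by 1.88 (SE 0.09), and the α-actinin gene Actn2 by 1.29 (SE 0.17). Of the 218 genes 29 changed by at least 2-fold (20 higher, 9 lower). Over all genes groups did not overlap for 17.1%, which chance gives for 10%.

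Other genes that rose were Khdc1a (1.69, SE 0.21), the testis kinase gene Smok4a (1.53, SE 0.23), Akr1c12, an aldo-keto reductase (1.44, SE 0.19), and Uaca (1.35, SE 0.24). Other genes that fell were Fndc1 (−1.05, SE 0.16), Rgs18, a regulator of G protein signalling (−0.94, SE 0.16), and Sytl2, a synaptotagmin-like gene (−0.87, SE 0.08). Smim5 (−1.13, SE 0.22), Camk4, a calcium/calmodulin-dependent kinase (−1.02, SE 0.19), and Tdrd5 (−0.98, SE 0.18) passed too. The calls of all 3 were lost when only DN3a arrays were fitted and with single arrays left out. Those arrays were Rptor−/− 1 (−0.95), Rptor−/− 3 (−0.98) or WT 1 (−1.05) for Smim5, Rptor−/− 1 (−0.82) or WT 3 (−0.83) for Camk4, and WT 1 (−0.88) for Tdrd5. The limma adjusted p ranged from 5.6e-10 for Cpa3 to 0.0094 for Smim5.

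In the type I interferon list 8 of 26 genes were higher in DN3a cells, none was lower and 18 did not pass (16 higher adjusted over the list alone), with a median of 0.34 (camera adjusted p = 5.59e-17). This list also passed with an estimated correlation (adjusted p = 0.0375). Oasl2, of the oligoadenylate synthetase-like family, was at 1.03 (SE 0.17). In Notch signalling and DN3 genes 3 of 24 were higher, none was lower and 21 did not pass (3 higher adjusted over the list alone; median 0.17, camera adjusted p = 9.31e-05, adjusted p = 0.138 with an estimated correlation). These were Dtx1, Mpzl2 and Ptcra, the pre-TCR α chain gene (0.68, SE 0.11). S phase genes shifted lower, with 1 of 31 lower, none higher and 30 not passing (3 lower adjusted over the list alone; median −0.20, −0.094 without Rptor−/− array 1; camera adjusted p = 8.04e-12, adjusted p = 0.338 with an estimated correlation). In G2/M and mitosis limma called 0 of 30 genes in either direction, 4 were lower at an unadjusted p under 0.05, and none passed adjusted over the list alone (median −0.21, camera adjusted p = 1.14e-06, adjusted p = 0.694 with an estimated correlation), and the list's call was lost without Rptor−/− array 1 (median −0.04). Dendritic-cell markers were lower as a list, with a median of −0.10 over 14 genes, 0 of them called by limma, 2 lower at an unadjusted p under 0.05 and 1 lower adjusted over the list alone (camera adjusted p = 0.00482, adjusted p = 0.138 with an estimated correlation). That call was lost without Rptor−/− array 1 (median −0.08).

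Metabolic lists that fell in ISP cells did not pass in DN3a cells. Medians were 0.036 for cholesterol synthesis (camera adjusted p = 0.655), −0.054 for MYC targets and ribosome biogenesis (0.0984), 0.0074 for oxidative phosphorylation (0.891) and −0.075 for glycolysis (0.411). The number of changed genes was 127 without Rptor−/− array 2, 144 without WT array 1, 124 without WT array 2 and 144 without WT array 3. It was 144 when only DN3a arrays were fitted and 377 after quantile normalization across all arrays. The share of higher genes was 84.0% with each array centred on its median, in place of 72.5%.

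In γδ T cells the genes with the largest rise in Rptor−/− included the receptor genes Klra5, Klrd1 and Klrh1 of the natural killer complex, at 3.14 (SE 0.20), 2.10 (SE 0.21) and 1.94 (SE 0.20) on the log2 scale. The chemokine genes Xcl1 and Ccl5 rose by 2.11 (SE 0.19) and 1.93 (SE 0.27), and the inhibitory receptor genes Lilrb4a and Cd200r1 by 2.56 (SE 0.18) and 2.40 (SE 0.12). Cd8b1, the CD8β chain gene, fell by 1.72 (SE 0.22). Birc5, which encodes survivin, fell by 0.96 (SE 0.19). By limma 677 genes changed, 393 higher and 284 lower, 43 of them by at least 2-fold (37 higher, 6 lower). Over all genes groups did not overlap for 21.0%, which chance gives for 10%.

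St6galnac2, a sialyltransferase gene, was at 2.50 (SE 0.45), with WT arrays at 7.58 ± 1.55 (SD, n = 3); the difference was 1.60 without WT array 1, and the call was lost when only γδ arrays were fitted (limma adjusted p = 0.0923). Plk2, a polo-like kinase, was at −1.50 (SE 0.25), and its call was lost in that fit too (limma adjusted p = 0.0504). Lbp, the lipopolysaccharide-binding protein gene, fell by 1.05 (SE 0.11), Ccr2, a chemokine receptor gene, by 0.99 (SE 0.16) and Cenph, a kinetochore gene, by 0.93 (SE 0.14). Gem, a small GTPase (−1.04, SE 0.27), and Shcbp1 (−0.94, SE 0.24) had limma adjusted p of 0.041 and 0.037. The Gem call was lost without Rptor−/− arrays 1 (−1.01) or 2 (−0.76) or WT arrays 1 (−1.17), 2 (−1.09) or 3 (−0.87). The Shcbp1 call was lost without Rptor−/− arrays 1 (−0.85), 2 (−0.98) or 3 (−1.01) or WT arrays 2 (−0.87) or 3 (−0.87). The other genes of this and the preceding paragraph had limma adjusted p from 4.0e-10 for Cd200r1 to 0.0067 for Birc5.

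In S phase and DNA replication 24 of 31 genes fell in γδ T cells, none rose and 7 did not pass (29 lower adjusted over the list alone; median −0.61, camera adjusted p = 2.2e-35, adjusted p = 0.118 with an estimated correlation). Thymidylate synthase (Tyms) was at −0.71 (SE 0.10), Uhrf1, a maintenance methylation factor, at −0.70 (SE 0.10), Mcm10 at −0.85 (SE 0.13) and DNA ligase I (Lig1) at −0.82 (SE 0.13). In G2/M and mitosis 16 of 30 fell, none rose and 14 did not pass (29 lower adjusted over the list alone; median −0.68, camera adjusted p = 2.47e-27, adjusted p = 0.118 with an estimated correlation). Ccnb2, cyclin B2, was at −0.81 (SE 0.15), Top2a, topoisomerase IIα, at −0.76 (SE 0.14) and the proliferation marker Mki67 at −0.74 (SE 0.13).

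In cytotoxic and NK-cell genes 8 of 19 rose, 2 fell and 9 did not pass (10 higher and 3 lower adjusted over the list alone; median 0.44, camera adjusted p = 2.12e-04, adjusted p = 0.118 with an estimated correlation). The median was 0.27 without Rptor−/− array 1 and 0.25 without WT array 3. Besides Klrd1 and Ccl5, the signalling adaptors Fcer1g and Tyrobp were at 1.65 (SE 0.13) and 1.07 (SE 0.19), whereas granzyme A (Gzma) was at −0.37 and the receptor gene Klre1 at −0.50 (limma adjusted p = 0.045 and 0.033). The Gzma and Klre1 calls were lost when only γδ arrays were fitted and without any 1 array except WT array 1 for Gzma and WT array 2 for Klre1. A set of 14 NK-cell genes, 6 of them in this list, was examined after the results were seen. It had a median of −0.045, with 1 gene higher and 2 lower by limma. Only 4 of these genes lay above the median level, so their median cannot exclude NK cells. In TCR signal strength and immediate early genes 3 of 27 rose, none fell and 24 did not pass (5 higher adjusted over the list alone; median 0.24, camera adjusted p = 1.64e-05, adjusted p = 0.118 with an estimated correlation), led by Tnfrsf9, the costimulatory receptor 4-1BB (1.52, SE 0.11). In the interferon list 4 of 26 rose, none fell and 22 did not pass (8 higher adjusted over the list alone; median 0.20, camera adjusted p = 3.04e-06, adjusted p = 0.145 with an estimated correlation), with Oasl1 at 0.70 (SE 0.13). Markers of myeloid cells were lower beside these groups, with a median of −0.19 over 20 genes, 0 of them called by limma, 5 lower at an unadjusted p under 0.05 and 2 lower adjusted over the list alone (camera adjusted p = 0.0179, adjusted p = 0.118 with an estimated correlation). The myeloid call was lost without Rptor−/− array 1 (median −0.15) or WT array 1 (median −0.11), and the median was 0.11 with genes below the median level removed.

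Of 52 oxidative phosphorylation genes, 4 were lower in Rptor−/− γδ T cells, none was higher and 48 did not pass (8 lower adjusted over the list alone; median −0.12, camera adjusted p = 5.83e-09, adjusted p = 0.147 with an estimated correlation). In glycolysis 4 of 19 were lower, 1 was higher and 14 did not pass (4 lower and 1 higher adjusted over the list alone; median −0.10, camera adjusted p = 0.0328, adjusted p = 0.355 with an estimated correlation). The glycolysis call was lost without Rptor−/− arrays 1 (median −0.08) or 2 (median −0.10) or WT array 3 (median −0.08). In the αβ-lineage list 4 of 29 were lower, none was higher and 25 did not pass (7 lower and 1 higher adjusted over the list alone; median −0.10, camera adjusted p = 0.0406, adjusted p = 0.401 with an estimated correlation). Cd8b1 belongs to this list, as does Dntt, terminal transferase, at −0.52 (SE 0.08), and the call was lost without Rptor−/− array 1 (median −0.10) or WT array 3 (median −0.04). The γδ-lineage list had 6 of 34 genes higher, 1 lower and a median of 0.078 (camera adjusted p = 0.0988). The number of changed genes was 363 without Rptor−/− array 2, 333 without WT array 2, 434 without WT array 3 and 345 when only γδ arrays were fitted. Centring each array on its median gave 74.3% higher genes in place of 58.1%.

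**Figure D3:**
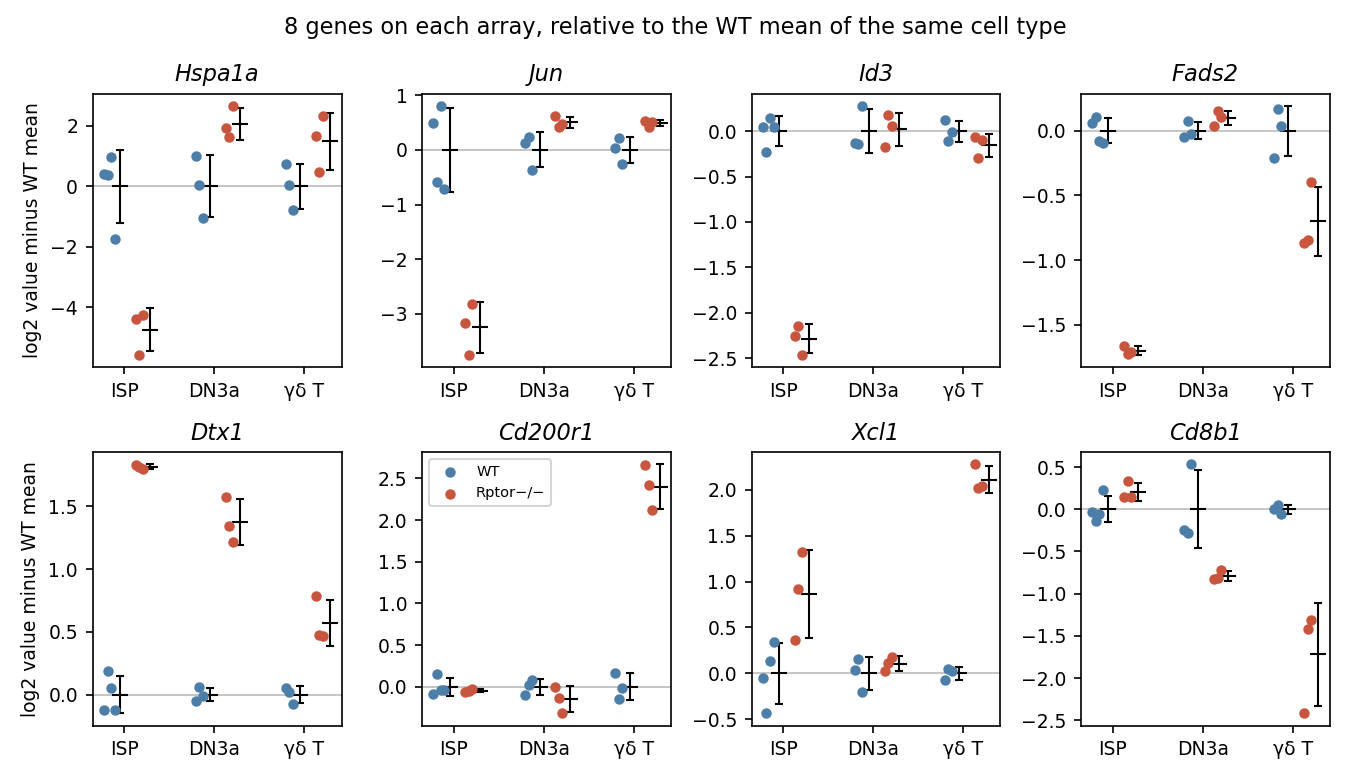
Log2 value of 8 genes on each array minus the WT mean of the same cell type, with WT in blue, Rptor−/− in red and the group mean ± SD in black. Hspa1a is lower by 4.74 in Rptor−/− ISP cells while its DN3a and γδ differences, 2.07 and 1.49, did not pass the test, and Cd200r1 is higher by 2.40 in γδ T cells.

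Genes changed in more than 1 population were counted against what independent lists would give. The real lists are not independent, since 1 fit gave each gene a shared spread and samples of different populations may be related. The Fisher p-values and expected counts below therefore do not measure a shared effect of genotype alone. Among higher genes ISP and DN3a cells shared 29 (9.27 expected, exact one-sided Fisher p = 3.9e-08), ISP and γδ T cells 63 (23.1 expected, p = 3.2e-13) and DN3a and γδ T cells 37 (2.80 expected, p = 6.8e-31). Among lower genes they shared 8 (3.94 expected, exact one-sided Fisher p = 0.042), 70 (18.7 expected, p = 1.6e-22) and 8 (0.768 expected, p = 9.4e-07). Genes called in opposite directions numbered 8, 15 and 2. Over all 22180 genes the effects correlated at Pearson r = −0.0104 for ISP with DN3a, 0.130 for ISP with γδ and 0.273 for DN3a with γδ T cells. In total 191 genes changed the same way in at least 2 populations, 104 without γδ WT array 2, 117 without γδ Rptor−/− array 2 and 62 when each pair of groups was fitted alone. Dtx1 was higher in all 3, at 1.81, 1.38 and 0.57 in ISP, DN3a and γδ cells, and Rptor lower in all 3.

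The WT comparison of γδ T cells with DN3a cells, which lay in 1 range of array medians, described the passage from precursor to γδ lineage. Il2rb, the shared IL-2 and IL-15 receptor β chain, was higher in γδ T cells by 5.21 (SE 0.14) on the log2 scale, and S1pr1, the receptor for thymic exit, by 5.10 (SE 0.10). Etv5, an ETS factor of γδ cells, was at 5.08 (SE 0.20), St6gal1, a sialyltransferase gene, at 5.06 (SE 0.23), Gimap4, a lymphocyte GTPase gene, at 4.92 (SE 0.18) and Il23r, the IL-23 receptor gene, at 4.91 (SE 0.13). Among lower genes Mpzl2 was at −4.98 (SE 0.19), Bst1, an ectoenzyme gene, at −4.56 (SE 0.12), Ptcra at −4.28 (SE 0.11), Ly6d at −4.23 (SE 0.13), Rag2, of the recombinase that assembles receptor genes, at −3.85 (SE 0.17) and Cdkn1a, a cyclin-dependent kinase inhibitor gene, at −3.70 (SE 0.19). By limma 5560 genes differed, 2824 higher and 2736 lower in γδ T cells, 897 of them by at least 2-fold (555 higher, 342 lower). Over all genes groups did not overlap for 38.9%, which chance gives for 10%. The limma adjusted p of these 12 genes ranged from 1.2e-17 for S1pr1 to 9.8e-12 for Cdkn1a.

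Of 34 γδ-lineage genes 29 were higher in WT γδ T cells than in DN3a cells, 2 were lower and 3 did not pass (29 higher and 3 lower adjusted over the list alone), with a median of 1.62 (camera adjusted p = 2.92e-26), including the transcription factor Maf at 4.25 and the chemokine receptor gene Ccr9 at 1.93. In TCR signal strength and immediate early genes 23 of 27 were higher, none was lower and 4 did not pass (24 higher and 2 lower adjusted over the list alone), with a median of 1.11 (camera adjusted p = 3.3e-19). Id3 was at 2.77 and Nr4a1 at 2.79. In cytotoxic and NK-cell genes 15 of 19 were higher, none was lower and 4 did not pass (15 higher adjusted over the list alone; median 0.81, camera adjusted p = 1.08e-10), with perforin (Prf1) at 1.96 and granzyme A (Gzma) at 1.60. In FOXO targets and quiescence genes 14 of 23 were higher, 2 were lower and 7 did not pass (15 higher and 2 lower adjusted over the list alone; median 0.65, camera adjusted p = 1.11e-07), with Foxo1 itself at 1.76 (1.01 when its probe sets were averaged) and Sesn3, a sestrin gene, at 1.34. Markers of mature αβ T cells moved with them, 9 of 17 higher, 3 lower and 5 not passing (11 higher and 3 lower adjusted over the list alone; median 0.67, camera adjusted p = 2.09e-06). Itgb7 was at 3.45 and Ctla4 at −2.61, and S1pr1 and Cd6 belong to other lists too.

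In MYC targets and ribosome biogenesis 31 of 37 genes were lower in WT γδ T cells, none was higher and 6 did not pass (31 lower adjusted over the list alone; median −0.54, camera adjusted p = 6.68e-19), with Myc at −1.68 and Gnl3, nucleostemin, at −1.28. In Notch signalling and DN3 genes 11 of 24 were lower, 3 were higher and 10 did not pass (11 lower and 4 higher adjusted over the list alone; median −0.26, −0.45 without WT γδ array 2; camera adjusted p = 1.93e-06), with Igfbp4 at 3.29 as a higher member. In cholesterol synthesis 14 of 19 were lower, 1 was higher and 4 did not pass (14 lower and 1 higher adjusted over the list alone; median −0.69, camera adjusted p = 1.11e-07, adjusted p = 0.0951 with an estimated correlation), with Sqle at −1.76. In S phase 19 of 31 were lower, 1 was higher and 11 did not pass (22 lower and 1 higher adjusted over the list alone; median −0.41, camera adjusted p = 1.11e-07, adjusted p = 0.338 with an estimated correlation). In fatty acid synthesis 5 of 16 were lower, none was higher and 11 did not pass (5 lower adjusted over the list alone; median −0.11, camera adjusted p = 0.0128, adjusted p = 0.32 with an estimated correlation), with Fads2 at −2.61. In the interferon list 12 of 26 were higher, 2 were lower and 12 did not pass (15 higher and 2 lower adjusted over the list alone; median 0.34, camera adjusted p = 2.84e-04, adjusted p = 0.285 with an estimated correlation), with Usp18 at 2.08 and Bst2 at −1.31. G2/M genes had 4 of 30 higher, none lower and 26 not passing (3 higher adjusted over the list alone; median 0.22, camera adjusted p = 0.0282, adjusted p = 0.752 with an estimated correlation). That call was lost without DN3a array 1 (median 0.065) or γδ arrays 2 (0.13) or 3 (0.17).

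Several lists did not pass in any genotype comparison. For lysosome and autophagy genes (35 measured) medians in ISP, DN3a and γδ cells were −0.045, 0.042 and 0.037 (camera adjusted p = 0.529, 0.144 and 0.0669). For mTORC1 and mTORC2 components (20 measured) they were −0.053, 0.015 and 0.025 (camera adjusted p = 0.185, 0.995 and 0.665). Markers of B cells had medians of 0.021, −0.047 and −0.034 (camera adjusted p = 0.676, 0.541 and 0.0669), erythroid markers of −0.013, −0.11 and −0.078 (0.676, 0.0729 and 0.214), and markers of thymic epithelium and stroma of −0.014, −0.012 and −0.087 (0.676, 0.541 and 0.0988). Of 4 sex-linked genes Xist was higher in Rptor−/− ISP arrays, at 11.85 ± 0.10 (SD, n = 3) against 11.19 ± 0.05 (SD, n = 4; limma adjusted p = 3.2e-06), and the Y-linked genes Eif2s3y, Kdm5d and Uty did not pass in any genotype comparison. Xist lay at 11.1 to 12.0 on every ISP array, so neither ISP group lacked cells that express it. Whether the ISP groups otherwise differed in the sex or pooling of animals is not known here. Such a difference would be part of the ISP genotype comparison.

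Whether the genotype effect differed between populations was tested by the interaction in limma. The Rptor effect in ISP cells differed from that in DN3a cells for 1554 genes (641 more positive and 913 more negative in ISP cells). Id3 (−2.31, SE 0.17), Fads2 (−1.80, SE 0.15), Dnajc15 (−1.93, SE 0.19) and Sqle (−1.48, SE 0.16) were more negative in ISP cells. Sidt1 (1.77, SE 0.15; 1.02 with its probe sets averaged), Mctp2 (1.41, SE 0.13) and the transcription factor gene Snai3 (1.33, SE 0.13) were more positive. Cpa3 passed too, but its signal lay below the median gene on all ISP arrays (2.25 to 2.41), where an effect could not be read, so its difference restates the fall in DN3a cells. The effect in γδ T cells differed from that in DN3a cells for 133 genes (87 more positive, 46 more negative). The receptor kinase gene Kit (1.72, SE 0.14) was more positive, and Lbp (−1.17, SE 0.15), Vwce (−1.04, SE 0.14) and Tnfrsf8, CD30 (−1.24, SE 0.17), were more negative. Cd200r1, Nt5e, which encodes the ectonucleotidase CD73, and Arhgap20 passed as more positive and Myof as more negative, but the first 3 lay below the median gene on all DN3a arrays and Myof on all γδ arrays, where an effect may not be readable. Kit was at −0.73 in DN3a cells and 0.99 in γδ T cells, and both passed. For γδ against ISP cells 1283 genes differed (805 more positive and 478 more negative in γδ T cells). Id3 (2.13, SE 0.17) was more positive, as were Cd200r1, Nt5e and Arhgap20, which lay below the median gene on all ISP arrays (2.45 to 2.69, 2.90 to 3.17 and 3.03 to 3.16). Sidt1 (−1.94, SE 0.15; −1.08 with its probe sets averaged), Lingo4 (−1.37, SE 0.13), Snai3 (−1.26, SE 0.13) and Ets2 (−1.24, SE 0.13) were more negative. In all, 130 of the 1554 genes, 55 of the 133 and 167 of the 1283 lay below the median gene on every array of at least 1 of the 2 populations.

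Lists told the populations apart as well. For ISP against DN3a cells 11 lists differed by camera, and cholesterol synthesis (median difference −0.74), MYC targets (−0.43), oxidative phosphorylation (−0.35), TCR signal strength (−0.50) and antioxidant genes (−0.22) also passed with an estimated correlation (adjusted p from 0.0038 to 0.0485). For γδ against ISP cells 13 lists differed, and cholesterol synthesis (0.62), MYC targets (0.55), TCR signal strength (0.62), antioxidant genes (0.24) and the αβ-lineage list (−0.41) passed with an estimated correlation too (adjusted p from 0.00747 to 0.0435). The TCR signal strength list holds immediate early genes such as Fos, for which stress at sorting of ISP cells was not ruled out. Its fall in ISP cells was also smaller without ISP WT array 4. For γδ against DN3a cells 8 lists differed by camera and 0 with an estimated correlation, where 1 had an unadjusted p under 0.05 and the lowest adjusted p = 0.436 with an estimated correlation. By fry 0 of the lists passed for that pair, 4 with an unadjusted p under 0.05. ISP arrays had lower medians than the others and were treated as a separate normalization, so a difference with ISP cells may hold a difference in scale. With arrays centred on their medians the share of more positive genes was 21.5% in place of 41.2% for ISP against DN3a and 79.5% in place of 62.7% for γδ against ISP. The 1554 genes were 1013 without DN3a WT array 1, and the 1283 were 853 without γδ WT array 3. The 133 genes were 76, 77, 77, 84, 85, 86 and 88 without γδ WT 2, γδ Rptor−/− 2, DN3a WT 2, DN3a Rptor−/− 2, DN3a WT 3, DN3a WT 1 and γδ WT 3, in that order.

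WT ISP cells were also set against WT DN3a and WT γδ cells, across the 2 ranges of array medians. By limma 21823 of 22180 genes differed between ISP and DN3a cells, 348 higher and 21475 lower in ISP cells, and 21781 between γδ and ISP cells, 21386 higher and 395 lower in γδ T cells. Median differences over all genes were −1.95 and 1.95. These counts follow the shift between array medians and cannot be read as differences between cell types. After quantile normalization 50.1% and 51.6% of the called genes were higher, and after median centring 73.0% and 29.9%, in place of 1.59% and 98.2%.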

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

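The tests of NK cells, of a lower γδ share, of dendritic or myeloid cells, of 1 ISP array and of a genotype effect alike in all cell types were chosen after the results were seen; the tests of handling stress, of DNA near Rptor and of other splits of the samples were fixed before.

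The genotype effect differed between populations by the interaction test for 1554 genes (ISP against DN3a), 133 genes (γδ against DN3a) and 1283 genes (γδ against ISP). Genes that stood out for ISP against DN3a were Cpa3 (1.88), Sidt1 (1.77), Mctp2 (1.41), Snai3 (1.33), Id3 (−2.31), Fads2 (−1.80), Dnajc15 (−1.93) and Sqle (−1.48). Those for γδ against DN3a were Cd200r1 (2.55), Kit (1.72), Nt5e (1.70), Arhgap20 (1.57), Lbp (−1.17), Vwce (−1.04), Myof (−0.94) and Tnfrsf8 (−1.24). Those for γδ against ISP were Cd200r1 (2.45), Nt5e (1.75), Id3 (2.13), Arhgap20 (1.51), Sidt1 (−1.94), Lingo4 (−1.37), Snai3 (−1.26) and Ets2 (−1.24). Of these genes Cpa3, Cd200r1, Nt5e and Arhgap20 lay below the median gene on all ISP arrays, the last 3 also on all DN3a arrays, and Myof on all γδ arrays. An effect may not be readable at such levels, above all a fall such as that of Cpa3. These differences alone therefore do not settle whether the effects differ.

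Median interaction effects of lists that differed by camera, ISP against DN3a, were 0.31 for αβ-lineage genes, −0.22 for antioxidant, −0.25 for ATF4 and amino acid, −0.74 for cholesterol, −0.28 for fatty acid, 0.47 for G2/M, −0.27 for glycolysis, −0.43 for MYC, −0.35 for oxidative phosphorylation, −0.25 for TCA cycle and −0.50 for TCR signal genes. Of these the αβ-lineage, ATF4, fatty acid, G2/M, glycolysis and TCA calls were lost, with adjusted p = 0.179, 0.0867, 0.0867, 0.378, 0.0867 and 0.36 with an estimated correlation. For γδ against DN3a the medians were −0.0581 for αβ-lineage, 0.37 for cytotoxic, −0.49 for G2/M, 0.0704 for MYC, −0.15 for oxidative phosphorylation, −0.33 for S phase, 0.0892 for TCR signal and −0.10 for interferon genes, and all 8 calls were lost, with adjusted p from 0.436 to 0.597 with an estimated correlation. For γδ against ISP they were −0.41 for αβ-lineage, 0.24 for antioxidant, 0.28 for ATF4 and amino acid, 0.62 for cholesterol, 0.0513 for cytotoxic, 0.29 for fatty acid, −0.93 for G2/M, 0.30 for glycolysis, 0.55 for MYC, 0.15 for oxidative phosphorylation, −0.20 for S phase, 0.14 for TCA cycle and 0.62 for TCR signal genes. Of these the ATF4, cytotoxic, fatty acid, G2/M, glycolysis, oxidative phosphorylation, S phase and TCA calls were lost, with adjusted p = 0.0566, 0.284, 0.107, 0.105, 0.166, 0.171, 0.402 and 0.304 with an estimated correlation.

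Single WT ISP arrays lay far from the other 3 for 8 of 74 genes looked at, by Dixon's criterion, where chance gives about 1 in 20. On WT array 2 Tox2 was 5.71 (others 5.38 to 5.42) and Lef1 10.31 (10.19 to 10.21). On WT array 3 Rptor was 6.34 (6.47 to 6.49), and on WT array 1 Usp18 was 5.56 (5.98 to 6.04). On WT array 4 Sod2 was 7.78 (8.07 to 8.13), Fdps 8.53 (8.97 to 9.04), Cd27 9.14 (8.68 to 8.73) and Sdhd 8.42 (8.64 to 8.68).

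In ISP cells the inducible heat shock and immediate early genes Hspa1a, Hspa1b, Hsph1, Jun, Fos, Fosb and Ier2 were lower in Rptor−/−, with a median of −2.30. No 1 array accounts for this, since the median nearest 0 with any ISP array left out was −2.09. An effect of the genotype alike in all cell types is argued against by DN3a cells, where the median was 0.429 and all 7 genes were positive. None of them passed there (limma adjusted p from 0.148 for Hspa1a to 0.966 for Ier2). The 95% interval of that median, 0.069 to 1.63, resamples these 7 genes, which may move together, and not the arrays. Stress at sorting that differed between ISP groups could produce such a pattern, and cannot be told apart from an effect of Rptor loss: 20 other stress genes had a median of −0.226 (−0.433 to −0.041), 9 lower and 0 higher by limma, and this interval spans the bound of −0.25 set before the test. An effect of Rptor on ISP cells themselves stays open as well, as immediate early genes also respond to T-cell receptor signals.

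The interferon list was higher in Rptor−/− cells of all 3 populations by camera, although only the DN3a call passed with an estimated correlation. DNA linked to the Rptor locus that differed between strains is argued against only as a change in the called list members themselves, since 0 of 15 lay among the 200 genes nearest Rptor. That result rests on gene positions alone. Neither a longer linked stretch nor an effect of a linked gene on distant ones was tested. Those 200 genes were called for 13.0% against 12.4% of others in ISP, 1.5% against 0.975% in DN3a and 4% against 3.04% in γδ T cells (exact two-sided Fisher p = 0.83, 0.451 and 0.404). Dendritic or myeloid cells in the Rptor−/− DN3a sort are argued against by 33 markers (median −0.106, 95% interval −0.155 to −0.049). These lay below the bound of 0.169 set from the list's own shift, as did the 10 above the median level (upper limit −0.0084). In the ISP sort the 33 markers had a median of −0.027 (−0.067 to 0.033), below the bound of 0.117. The same 10 had an upper limit of 0.072 there. Their level was taken over all arrays together, and ISP arrays had lower medians. These markers may thus give weak signal on ISP arrays, so such cells cannot be told apart from a response in ISP cells. The intervals resample markers and not arrays. In γδ T cells the 33 markers had a median of −0.166 (−0.198 to −0.048), but the interval of those 10 (−0.176 to 0.134) spans the bound of 0.101, so such cells cannot be told apart from a response there. The γδ gate left out Gr1-positive cells, which are only part of these cell types. An interferon response to Rptor loss stays open as a hypothesis, and litter, housing or infection of the animals was not tested.

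In γδ T cells the cytotoxic and NK-cell list was higher in Rptor−/− by camera, a call lost with an estimated correlation (camera adjusted p = 0.118). The γδ gate left out NK1.1-positive cells, but the purity of the sort is not known here. NK cells in that sort cannot be told apart from a change in γδ T cells: 14 NK-cell genes, 6 of them also in the list, had a median of −0.045 (95% interval −0.287 to 0.087), below the bound of 0.219 set from the list's own shift, but only 4 lay above the median level, with an interval of −0.414 to 1.28. A lower share of γδ T cells, which would raise the markers of other cell types, cannot be told apart either. The 72 markers of dendritic, myeloid, B, erythroid and stromal cells had a median of −0.111 (−0.173 to −0.038). The 22 above the median level had an interval of −0.158 to 0.088, and those below it may hide a small share. Genes of the αβ lineage were not among these markers. Their list was lower by camera (median −0.10), a call lost with an estimated correlation (camera adjusted p = 0.401). A change in which γδ subsets are present, or in their state, may explain the pattern and was not tested.

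Other splits of the samples bear on the counts of changed genes. For ISP cells 1 of 35 splits, the real one, gave as many genes (2759, highest other 1342), a share under 0.05. The same held for WT ISP against DN3a (1 of 35, 21823 and 21079) and WT γδ against ISP (1 of 35, 21781 and 21023). The counts of these WT comparisons follow the shift between array medians. A random division of the arrays is thus an unlikely source of the ISP count. The splits cannot tell genotype from any other difference between the groups' samples. For DN3a (218, highest other 1), γδ (677, highest other 2) and WT γδ against DN3a (5560, highest other 0), the real split was 1 of 10, and 10 splits are too few for a share under 0.05. For the interactions 100 splits were drawn of 700, 200 and 700. For ISP against DN3a 2 of 100 gave as many (1554, highest other 1559), for γδ against DN3a 3 of 100 (133, highest other 388) and for γδ against ISP 1 of 100 (1283, highest other 1098). These splits decide nothing about a difference between populations, since those with high counts keep the genotypes of 1 population apart and exchange or mix those of the other. The split with 388 genes, several times the real 133, points to that structure of the samples, with γδ genotypes apart and DN3a genotypes mixed.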

How the results depend on the processing

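The fit of only the 12 DN3a and γδ arrays was chosen after seeing the data, and all other alternatives were planned. No count of changed genes in ISP cells moved by over 1.5 times with an array left out (1899 to 2671). Of 315 gene calls, the trended variance model lost 0 and gained 9, median centring lost 14, quantile normalization 8, array weights 11, every probe set alone 29, a fit of only the arrays compared 54 and the replicate number as a block 131; of 2148 calls over arrays left out, 186 were lost. None of these gene values reversed. The causes of these losses were not tested. With genes below the median level removed, the myeloid list in γδ T cells turned to 0.11 (adjusted p = 0.977).

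With at least 2-fold required, counts were 112 (ISP), 29 (DN3a), 43 (γδ), 897 (WT γδ against DN3a), 183, 47 and 165 (interactions ISP−DN3a, γδ−DN3a and γδ−ISP) and 6 genes shared by populations. With only the arrays compared they were 1313, 144 and 345 for ISP, DN3a and γδ, and 62 shared. DN3a gave 377 after quantile normalization. Every probe set alone gave 40222 and 40111 for WT ISP against DN3a and γδ against ISP, and 83 for γδ−DN3a. With genes below the median level removed these 2 WT counts were 10783 and 10753, with 297 shared. Lists that passed with an estimated correlation numbered 8 (ISP), 1 (DN3a), 0 (γδ, with 8 at an unadjusted p under 0.05 and 7 by fry), 7 (WT γδ against DN3a), 5, 0 and 5 (interactions); fry gave 0 for γδ−DN3a.

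With each array left out in turn, counts were 124 to 254 (DN3a), 333 to 782 (γδ), 1013 to 1647, 76 to 161 and 853 to 1308 (interactions) and 104 to 199 shared. Lists passing were 3 to 6 (DN3a), 6 to 14 (γδ), and 14 to 15 (ISP). Rptor ranged from −0.31 to −0.18 in ISP cells and from −0.33 to −0.27 in γδ T cells, with adjusted p from 0.019 to 0.22 and 0.0713 to 0.156.

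Rptor kept its sign but lost its call in ISP cells with every probe set alone (−0.24, adjusted p = 0.0504) and only the arrays compared (−0.24, 0.128). In γδ T cells it did so with every probe set alone (−0.30, 0.0875), only the arrays compared (−0.30, 0.114), median centring (−0.27, 0.0698), array weights (−0.31, 0.05) and the 12 DN3a and γδ arrays (−0.30, 0.0605).

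Replicate numbers were shared between groups, and were not taken to pair the arrays because not every correlation was over 0.1. Deviations of same-numbered arrays correlated at −0.013 to 0.099 in ISP (0 of 3 over 0.1), 0.013 to 0.242 in DN3a (2 of 3) and −0.104 to −0.003 in γδ T cells (0 of 3), and 1, 2 and 0 of 3 correlated best with their own number. For WT γδ with WT DN3a cells correlations were 0.026 to 0.099 (0 of 3 over 0.1), and all 3 correlated best with their own number, a hint from the data that numbers may be shared. With the replicate number as a block limma called 0 genes in ISP cells (4063 at an unadjusted p under 0.05), 275 in γδ T cells, 65 for γδ−DN3a, 793 for γδ−ISP and 23 shared, and Rptor was −0.23 (ISP) and −0.30 (γδ). Of 73 list calls the block lost 4, Notch and p53 targets in ISP cells and αβ-lineage and glycolysis in γδ T cells. List alternatives planned for the 2 WT comparisons that cross the normalization sets were not run.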

Other observations

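The gene families below were chosen after the results were seen, as were the tests of them. Of 12 families examined by symbol, mitochondrial ribosomal proteins and proteasome subunits were lower in Rptor−/− ISP cells by camera with either correlation. Of 71 mitochondrial ribosomal protein genes 52 were lower and 0 higher by limma, with a median of −0.39 (−0.31 after quantile normalization, −0.44 after median centring; camera adjusted p = 1.0e-31, adjusted p = 0.0384 with an estimated correlation), among them Mrpl36 at −1.02 and Mrpl12 at −0.81. Of 38 proteasome subunit genes 25 were lower and 0 higher, with a median of −0.28 (−0.21 and −0.33 under these scalings; camera adjusted p = 4.03e-19, adjusted p = 0.024 with an estimated correlation), among them Psma1 at −0.55 and Psmd1 at −0.64. Of 18 cytosolic aminoacyl-tRNA synthetase genes 13 were lower and 0 higher, with a median of −0.34 (camera adjusted p = 6.42e-11, adjusted p = 0.0534 with an estimated correlation). Of 9 chaperonin CCT genes 3 were lower and 1 higher (median −0.23, camera adjusted p = 0.0098, adjusted p = 0.346 with an estimated correlation), and 11 of 66 cytosolic ribosomal protein genes were lower, with a median of −0.055 (camera adjusted p = 8.2e-04, adjusted p = 0.346 with an estimated correlation). In DN3a cells the medians of the mitochondrial ribosomal, proteasome, synthetase and cytosolic ribosomal families were 0.038, 0.00077, −0.038 and 0.022, and none passed by camera. In γδ T cells 1 of 38 proteasome genes was lower and 0 higher, with a median of −0.11 (camera adjusted p = 2.29e-06, adjusted p = 0.155 with an estimated correlation). The mitochondrial ribosomal, synthetase and cytosolic ribosomal families did not pass there. Chaperonin CCT, histone and Klra receptor genes passed by camera in γδ T cells (medians −0.12, −0.079 and 0.084, camera adjusted p = 0.0383, 3.85e-04 and 0.025). With an estimated correlation these calls were lost (camera adjusted p = 0.486, 0.139 and 0.183).

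Interferon-inducible GTPase genes (Gbp, Irgm, Igtp and Iigp families), which defend against intracellular pathogens, passed by camera in all 3 populations, and with an estimated correlation in DN3a cells alone. In ISP cells 8 of 14 were higher and 1 lower (median 0.52, camera adjusted p = 5.08e-06, adjusted p = 0.0621 with an estimated correlation). In DN3a cells 4 were higher (median 0.36, camera adjusted p = 4.4e-08, adjusted p = 0.0434 with an estimated correlation), and in γδ T cells 4 (median 0.36, camera adjusted p = 2.29e-06, adjusted p = 0.139 with an estimated correlation). Igtp was at 0.84, 0.75 and 0.50. The direction was positive under both scalings in all 3. H2-Q and H2-T class I genes passed by camera in all 3 populations too. In DN3a cells 0 of 7 genes were called by limma and 5 were higher at an unadjusted p under 0.05 (median 0.31, camera adjusted p = 1.34e-04, adjusted p = 0.0484 with an estimated correlation). In ISP cells 3 were higher (median 0.15, camera adjusted p = 0.0107, adjusted p = 0.185 with an estimated correlation), and in γδ T cells 4 (median 0.49, camera adjusted p = 0.00182, adjusted p = 0.139 with an estimated correlation), led by H2-Q5 at 1.83 (SE 0.31); their probe sets read near-identical copies, and the γδ median was 0.49 after quantile normalization. Trim30 and Ifi200 genes had 2 of 11 higher in DN3a cells (median 0.37, camera adjusted p = 1.53e-08, adjusted p = 4.27e-04 with an estimated correlation), and did not pass in ISP (camera adjusted p = 0.309) or γδ T cells (0.134).

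T-cell receptor α or δ variable segments, read as a family of 5, had 4 members higher in Rptor−/− ISP cells (median 0.98), 0 changed by limma in Rptor−/− DN3a (median 0.0046, 1 with an unadjusted p under 0.05) or γδ T cells (median −0.08, 0 with an unadjusted p under 0.05), and 4 higher in WT γδ T cells than in DN3a cells (median 3.24).

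Genes changed in all 3 populations were 9 higher (0.164 expected from independent lists) and 3 lower (0.0505 expected). The lists shared an estimate of each gene's spread and were not independent, so these expected counts are only a rough guide. Beside Dtx1 the higher genes were Afdn, Arrdc4, Blcap, Ifih1, Igtp, Iigp1, Plin2 and Tnfrsf18, and the lower genes were Rptor, Atp8b4 and Lgals1. Some calls were narrow, as for Iigp1 (limma adjusted p = 0.033, 0.044 and 0.0496 in ISP, DN3a and γδ cells). In γδ T cells Ifih1 and Rptor had limma adjusted p of 0.047 and 0.049. For Dtx1 and Tnfrsf18 the highest limma adjusted p of the 3 populations was 0.0034 and 0.0070. Tnfrsf18, which encodes the costimulatory receptor GITR, was at 0.77, 0.50 and 0.56 in ISP, DN3a and γδ cells. Blcap was at 0.77, 0.72 and 0.51, and Nnat, which lies within Blcap, was at 4.10 in ISP cells and −0.06 and 0.56 in the others, where it did not pass.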
